A study of Mus musculus with 37 samples.

How the data were processed

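Gene expression was measured in spleen RNA of 37 male MutaMouse animals, each on 1 array, in 8 groups of 4 or 5 animals (3 DBC doses and a vehicle control at each of 2 harvest times). Each animal is a replicate. The labels speak of 5 animals per group and time. The groups control_4h, mid_4h and mid_24h had 4 arrays each, and no source used here says why. Animals harvested at 72 h have no arrays in the series and were not analysed here. Spleen RNA, 200 ng of each sample, carried Cy5 and the universal mouse reference RNA carried Cy3, per the labels' protocols, with no array on which the dyes were exchanged. The vehicle was olive oil at 0.005 ml per g body weight, per the labels' protocols.

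The arrays were scanned and quantified with Agilent Feature Extraction 11.0.1.1 under protocol GE2_1100_Jul11, per the file headers. The scanner tables hold raw median signal and local background intensity for each spot and channel, and a processed intensity that the program had background-subtracted, detrended and dye-normalized, per the file headers. The deposited values are log2 ratios of Cy5 over Cy3, a single one for each probe and array. How the authors normalized that table is not given in the sources used here. Its medians per array lay between −0.029 and −0.014. Its values followed loess-normalized log2 ratios of the median signals without background subtraction with a slope of 0.993 to 0.998 and r of 0.997 to 0.999 across probes, so its direction is spleen over reference and its centre is near 0.

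An array held 62976 features, of which 3671 were controls. The other 59305 came from 55681 probes. Gene symbols were taken from the RefSeq accession that the array tables give for a probe. A list of accessions and symbols matched 27235 probes to 1 symbol each and left 28446 without one. The array annotation refers to mm9 and that list to another build, so no coordinates are given. Between 20676 and 31839 spots per array stood well above background in Cy5, and between 198 and 380 spots were marked by the scanner software as outliers and left out. No spot was saturated (0 per array). The replicate arrays of a group correlated at r between 0.896 and 0.973. The number of arrays per group limits the precision.

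Median signals were background-corrected with normexp at an offset of 50 and normalized with loess within each array, with control spots at weight 0 and no step between arrays. Replicate spots of a probe were averaged. Probes well above background in Cy5 on at least 4 arrays were kept (29627). Where a gene had several probes, the one with the highest mean intensity stood for the gene. R 4.3.3, limma 3.58.1 and the data.table package (version 1.17.8) were used.

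limma fitted a mean for each of the 8 groups to all 37 arrays, without a term for slide. Benjamini-Hochberg adjusted p under 0.05 was called a change. The comparisons were each dose against the control of its harvest time, the trend over the 4 dose groups in order at each time, the difference of the high-dose effect between 24 h and 4 h, and the controls of 24 h against those of 4 h. All tests were two-sided. Gene lists were tested on 14090 genes with camera at a preset correlation of 0.01, adjusted over the 26 lists of a comparison, with 45 missing values filled by the group mean. A list score is the mean log2 ratio of its measured genes. The lists covered p53 targets, AHR and xenobiotic metabolism, NRF2 targets, DNA repair and checkpoint, cell cycle, B cells, germinal centre B cells, plasma cells, T cells, NK and cytotoxic cells, erythroid genes, heme synthesis, neutrophils, macrophages and monocytes, dendritic cells, megakaryocytes and platelets, stroma and endothelium, interferon response, inflammatory cytokines and NF-kB targets, glucocorticoid response, immediate early genes, circadian clock, haematopoietic progenitors, pancreas, adipose tissue, and skeletal muscle with blood-borne liver RNA. Correlations between comparisons were set beside 20 simulations of unchanged groups, drawn with independent noise and without slide effects.

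Genes were named by rule. The rule took the 6 largest rises and falls of a dose comparison (4 of the other comparisons) among called genes well above background on every array of the brighter group, up to 4 members of a described list with the smallest adjusted p, and a fixed set of markers. Comparisons, lists, this rule and the alternatives were chosen before the data were examined, except for the pancreas score as a covariate, which was added afterwards.

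The alternatives were no background subtraction, the processed intensities, the Cy5 channel alone scaled to the array's 75th percentile, the deposited log2 ratios, no filter, a stricter filter (22014 probes), a fold change of at least 1.5, slide as a block, replicate number as a block within each harvest time, each harvest time fitted alone, array weights and leaving out each array. For lists they were camera with an estimated correlation, fry, slide as a block and Cy5 alone. Values of a channel alone came from the processed intensities, which had been dye-normalized. fry asks whether the genes of a list move one way on balance and does not compare the list with other genes. Slides were read from the array numbers in the file headers. There were 5 slides and 4 scan days, with slides 4 and 5 scanned on the same day. Slides 1 and 4 held 1 array of each group. Slides 2, 3 and 5 did too, apart from mid_4h on slide 2, control_4h on slide 3 and mid_24h on slide 5.

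The fit was tested on simulated data with the real probes (24 h high dose against control, 5 runs, 200 changed probes each). It called 38.8% of the probes changed by 0.5 on the log2 scale, 90% of those changed by 1 and 100% of those changed by 2 or 3, and 5.73% of the calls were false. The simulated noise was independent between probes and arrays and held no slide effects. These shares therefore need not hold for the real arrays.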

Results

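Transcript levels were measured in the spleens of adult male MutaMouse animals, a transgenic strain that carries a bacterial reporter gene for scoring mutations. The animals had been given dibenzo[def,p]chrysene (DBC), a polycyclic aromatic hydrocarbon, in olive oil by gavage, that is, through a tube into the stomach, once a day for 3 days. Spleens were taken 4 h or 24 h after the last dose, and each spleen RNA was hybridized to its own 2-colour array together with a common mouse reference RNA. Every value is therefore a log2 ratio of spleen (Cy5) over reference (Cy3). The 4 h groups held 4 control, 5 low-dose (2.0 mg/kg per day), 4 mid-dose (6.3 mg/kg per day) and 5 high-dose (20.0 mg/kg per day) animals. The 24 h groups held 5 control, 5 low-dose, 4 mid-dose and 5 high-dose animals. Between 34.9% and 53.7% of the spots of an array stood well above background in Cy5, from 34.9% to 40.3% on slide 5 and from 49.6% to 53.7% on slide 3. Over 14090 genes, 38.2% of the variance lay between the 8 groups, 31.1% between slides within groups, and 30.7% was left. The slides were laid out as blocks, with at most 1 array of a group on each, and the main fit kept the slide share in its error. Because of that slide share, counts of calls are also given with slide as a block. So are the genes and lists named here whose call the block changed. The number of arrays limits the precision of every comparison.

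Each dose was set against the vehicle control of the same harvest time to ask which spleen transcripts differ after DBC, at which dose and how long after the last one. At the high dose, 4 h after the last dose, red-cell genes were among the largest falls. Slc4a1, the anion exchanger of the red-cell membrane, changed by −6.21 ± 0.64 on the log2 scale (SE, 5 high-dose against 4 control animals, limma adjusted p = 4.24e-08). The beta-globin gene Hbb-bs was lower by a log2 change of −6.15 ± 0.62, Bpgm, whose product regulates the release of oxygen from hemoglobin, by −4.98 ± 0.37, and Fech, the enzyme that puts iron into heme, by −4.49 ± 0.40. Of the 35 measured genes of the erythroid list, 32 were lower and 0 higher, with the same counts when adjusted over the list alone, and their median change was −3.40. Alas2, a member of the erythroid list, changed by −4.29 ± 0.48, a call that the processed intensities lost. All 12 measured heme synthesis genes were lower, with a median of −2.29, among them Urod at −2.95 ± 0.36. The erythroid score of the high-dose arrays was −3.25 ± 0.24 (SD, n = 5) relative to the control mean in the plot of list scores, and the fall was between −3.88 and −2.78 on each of the 4 slides that held both groups. The preset-correlation test camera gave adjusted p = 1.54e-52 for the erythroid and 9.94e-24 for the heme list, and both held with an estimated correlation (0.00843 and 0.0255). With slide as a block and an estimated correlation the erythroid list held (0.032) and the heme list did not (0.129).

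Genes of dividing cells were lower as well. Mki67, a marker of cycling cells, changed by −3.35 ± 0.39 and Ube2c, which marks mitotic proteins for destruction, by −3.23 ± 0.38 at 4 h. Of 45 measured cell cycle genes 38 were lower and 0 higher (43 and 0 adjusted over the list alone), with a median of −1.46 and a fall on each of the 4 slides. camera gave adjusted p = 6.13e-48, with an estimated correlation 0.0291, and 0.137 with an estimated correlation and slide as a block. Of 39 DNA repair and checkpoint genes 11 were lower (12 adjusted over the list alone), among them Brca2 at −1.33 ± 0.25 and the ligase Lig1 at −1.47 ± 0.28. The median of that list was −0.17, with camera adjusted p = 2.41e-05 and adjusted p = 0.16 with an estimated correlation. Of 24 genes of neutrophils and their precursors 11 were lower (12 lower and 1 higher adjusted over the list alone), among them the granule protein gene Camp at −3.75 ± 0.61 and S100a8 at −2.41 ± 0.39. The neutrophil score of the high-dose arrays was −1.01 ± 0.14 (SD, n = 5), and the list had a median of −0.69, with camera adjusted p = 5.95e-09 and adjusted p = 0.23 with an estimated correlation. In Cy5 alone its median was −1.56 at 4 h and −1.20 at 24 h.

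The higher transcripts changed by smaller amounts. Phlda3, a p53 target that restrains Akt signalling, rose by 0.87 ± 0.12 (adjusted p = 2.81e-06), and the cell cycle inhibitor Cdkn1a by 0.63 ± 0.18 (adjusted p = 0.0213). Of 38 p53 targets 4 were higher and 2 lower (8 and 2 adjusted over the list alone). Their median was 0.22 and camera gave adjusted p = 0.0476, or 0.27 with an estimated correlation. Mdm2 at 0.15, Bax at 0.28 and Ccng1 at 0.43 were not called, although Bax and Ccng1 were with slide as a block (adjusted p = 0.0299 and 0.00529). Among the largest rises, Ncmap at 1.36 ± 0.41, Adcy5 at 1.28 ± 0.34 and the matrix protein gene Mgp at 1.21 ± 0.31 stood beside the RNA-binding protein gene Cirbp at 1.15 ± 0.15 (adjusted p = 1.5e-06). Dbp, a transcription factor under the circadian clock, rose by 0.86 ± 0.15, and of 16 circadian genes 3 were higher (6 adjusted over the list alone, camera adjusted p = 0.00719, with an estimated correlation 0.27). The circadian score was higher on each of the 4 slides that held both groups, by 0.298 to 0.411. Of 25 stroma and endothelium genes 3 were higher (6 adjusted over the list alone), with a median of 0.43, camera adjusted p = 2.41e-04 and 0.16 with an estimated correlation.

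limma called 619 probes higher and 1653 lower of 29627 at the high dose and 4 h, from 476 and 1031 genes with a symbol. With slide as a block 2232 were higher and 2479 lower, so that 52.6% of the calls were lower against 72.8% without the block, and all 2272 calls were made in the same direction. Without control_4h replicate 1 the count was 1343, with the higher calls down to 167 and the lower calls to 1176, so that 87.6% were lower. Without high_4h replicate 2 the higher calls were 412.

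**Figure D1:**
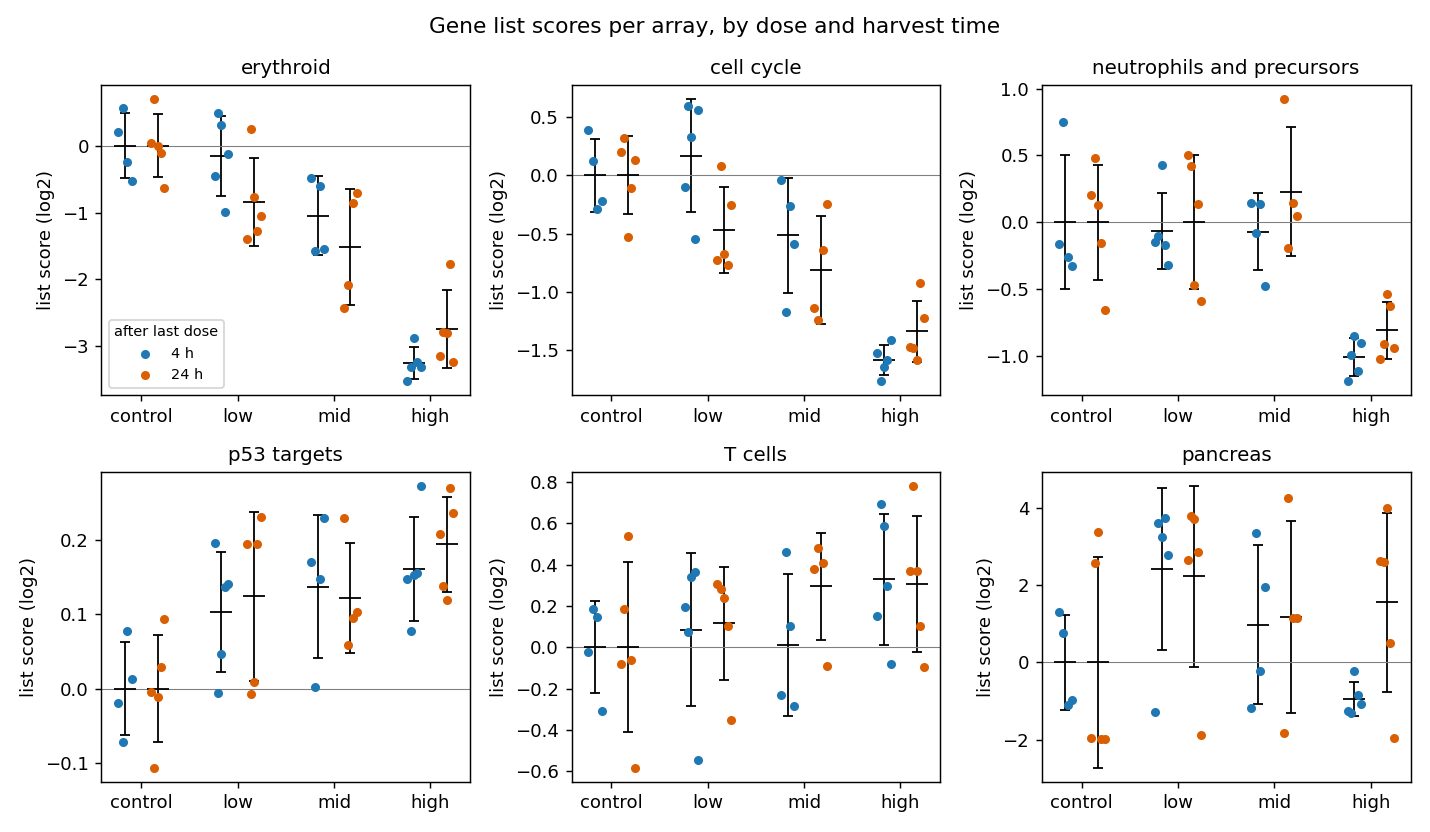
Score of 6 gene lists per array (mean log2 ratio of the list's genes relative to the control mean of the same harvest time), by dose, with 1 point per animal and mean ± SD, 4 h in blue and 24 h in orange. The erythroid scores of the high-dose arrays had means of −3.25 at 4 h and −2.75 at 24 h.

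Red-cell genes were again among the largest falls at the high dose at 24 h. Slc4a1 changed by −5.27 ± 0.60 (SE, 5 against 5 animals, adjusted p = 5.62e-07), Bpgm by −4.00 ± 0.35, Fech by −3.81 ± 0.38 and Alas2 by −2.95 ± 0.46. The processed intensities lost the call of Alas2 here as well. Of 35 erythroid genes 29 were lower (31 adjusted over the list alone), with a median of −3.04 and a fall between −3.49 and −1.67 on each of 5 slides. All 12 heme synthesis genes were lower, with a median of −2.01, and 37 of 45 cell cycle genes were lower (40 adjusted over the list alone), with a median of −1.31 and Mki67 at −2.87 ± 0.37. camera gave adjusted p = 8.17e-51 for the erythroid, 8.83e-26 for the heme and 3.25e-46 for the cell cycle list, and with an estimated correlation 0.0102, 0.0173 and 0.0339. The block by slide with an estimated correlation gave 0.0494, 0.0728 and 0.0903. Of 39 DNA repair genes 8 were lower (12 adjusted over the list alone, camera adjusted p = 7.83e-04, with an estimated correlation 0.236). Of 24 neutrophil genes 8 were lower (13 adjusted over the list alone, camera adjusted p = 7.05e-09, with an estimated correlation 0.2), with Camp at −2.57 ± 0.57 and S100a8 at −1.60 ± 0.37.

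Among the rises at 24 h were Errfi1, a feedback inhibitor of the EGF receptor, at 1.34 ± 0.28 (adjusted p = 0.00176), the glucocorticoid-induced Fkbp5 at 0.95 ± 0.23 and the retinoic acid hydroxylase Cyp26b1 at 0.94 ± 0.18. The p53 targets Phlda3 at 0.69 ± 0.11, Bbc3 at 0.78 ± 0.15, Cdkn1a at 0.59 ± 0.17 and Ccng1 at 0.47 ± 0.13 were higher, and Ppm1d at −0.56 ± 0.14 was lower. With 4 of 38 p53 targets higher and 1 lower (7 and 1 adjusted over the list alone), the median was 0.24 and the list was higher on each of 5 slides (camera adjusted p = 0.00152, with an estimated correlation 0.0737). Of 17 glucocorticoid and stress response genes 4 were higher and 1 lower (6 and 1 adjusted over the list alone), with a median of 0.27 and camera adjusted p = 0.0101, or 0.18 with an estimated correlation. In the circadian list 2 genes were higher (7 adjusted over the list alone, camera adjusted p = 3.57e-04, with an estimated correlation 0.137). The circadian score was higher on each of 5 slides, by 0.215 to 0.413. limma called 208 probes higher and 1241 lower, from 166 and 828 genes, and 1252 and 2119 with slide as a block. The share lower was 85.6% without and 62.9% with the block, and all 1449 calls were made in the same direction with it. The rises rested more on single arrays. Their number was 90, 102 and 136 without control_24h replicate 1, 2 or 5, 319 without control_24h replicate 3, 112 without high_24h replicate 2, and 138 without high_24h replicate 1 or 3.

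Lymphocyte and macrophage genes had medians near or above those of the controls at the high dose. The median of 30 T cell genes was 0.33 at 4 h, with 1 higher and 0 adjusted over the list alone, and 0.35 at 24 h, with 3 higher and 4 adjusted over the list alone. Zap70, a kinase of the T cell receptor, rose by 0.63 ± 0.16 at 24 h. camera gave adjusted p = 0.00751 at 4 h and 5.05e-04 at 24 h, but with an estimated correlation 0.741 and 0.623. On 1 of the 5 slides at 24 h the T cell list lay lower, at −0.17. The median of 32 B cell genes was 0.23 at 4 h (0 called, camera adjusted p = 0.0433, with an estimated correlation 0.741) and 0.10 at 24 h (1 higher, 0 adjusted over the list alone, camera adjusted p = 0.161). Cd3e, a chain of the T cell receptor complex, at 0.32 and 0.34 was not called. The median of 27 macrophage and monocyte genes was 0.35 at 4 h (1 higher, 0 adjusted over the list alone, camera adjusted p = 0.0171) and 0.34 at 24 h (0 higher, 7 adjusted over the list alone, 0.00161), with an estimated correlation 0.741 and 0.623.

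DBC is metabolised by enzymes under the aryl hydrocarbon receptor (AHR), so that list was examined as well. Cyp1a1, the best-known target of the receptor, stood well above background in Cy5 on 0 of 37 arrays. Cyp1b1 was 0.61 higher at 4 h (adjusted p = 0.103) and 0.58 higher at 24 h (adjusted p = 0.139), and was called at both times only with slide as a block (0.0225 and 0.0122). Tiparp stood at 0.26 and 0.14. Of 11 measured AHR and xenobiotic genes only the epoxide hydrolase gene Ephx1 was called at 4 h, at 0.51 ± 0.13 (2 higher and 1 lower adjusted over the list alone, median 0.26, camera adjusted p = 0.073). In Cy5 alone Ephx1 was not called, and 0 genes of the list were higher and 1 lower. At 24 h 0 of 11 were called by limma, with a median of 0.05, while with slide as a block Ephx1 at 0.31 was called besides Cyp1b1 (adjusted p = 0.0496). In Cy5 alone 1 gene of the list was higher and 1 lower at 24 h. Of 20 NRF2 targets, the genes of the oxidative stress response, the glutathione synthesis genes Gclm at −1.48 ± 0.27 and Gclc at −1.05 ± 0.22 were lower at 4 h, and Nqo1 at −0.78 was called only with slide as a block (adjusted p = 0.0139). The list gave camera adjusted p = 0.37 at 4 h, with 1 higher and 4 lower adjusted over the list alone, and 0.395 at 24 h. At 24 h its median was 0.02 while its mean was −0.09 and the test pointed down.

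Among the largest falls outside the red-cell lists were the palmitoyltransferase gene Zdhhc22, at −5.48 ± 0.69 at 4 h, and Rsad2, an antiviral gene known for its induction by interferon, at −5.31 ± 0.41 at 4 h and −4.58 ± 0.39 at 24 h. The interferon-induced Isg15 was lower at −1.51 ± 0.23 and −1.30 ± 0.22. Other interferon genes went the other way at 4 h, with Ifit3 at 0.96 ± 0.26 and Ifi27l2a at 0.95 ± 0.23. Of 30 interferon response genes 4 were higher and 2 lower at 4 h (9 and 2 adjusted over the list alone), and 0 higher and 3 lower at 24 h (3 and 3 adjusted over the list alone). camera gave adjusted p = 0.0875 and 0.161, with medians of 0.30 and 0.31.

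The mid dose gave fewer calls. At 4 h it called 119 genes, counted by the probe that stood for each gene. Of these, 115 were called lower at both the mid and the high dose. Independent lists would share 7.98, and the control animals are the same. Rsad2 changed by −2.97 ± 0.43 (SE, 4 against 4 animals), Bpgm by −2.65 ± 0.39, the pseudogene Cyp4b1-ps2 by −2.88 ± 0.44 and Fech by −2.10 ± 0.42. The higher probes were 4, those of Cdkn1a at 0.98 ± 0.19 (adjusted p = 0.00267), Phlda3 at 0.65 ± 0.12 (0.00247), Cirbp at 0.67 ± 0.16 and, named after the values were seen, Ptp4a2 at 0.43 ± 0.11. The erythroid list had 2 of 35 genes lower (16 adjusted over the list alone), the heme list 1 of 12 (7), the cell cycle list 0 of 45 (0) and the p53 list 2 of 38 higher (4). Their medians were −0.996, −0.99, −0.48 and 0.11, with camera adjusted p = 4.24e-19, 1.78e-13, 6.17e-18 and 0.00132. With an estimated correlation these were 0.182, 0.182, 0.329 and 0.182. The cell cycle list was lower on 2 of 3 slides, and the p53 list was higher on 3 of 3. limma called 4 probes higher and 283 lower, and 37 and 387 with slide as a block. Both fits called 284 of them in the same direction. Without control_4h replicate 2 the count was 154, without mid_4h replicate 2 it was 161 and without mid_4h replicate 4 it was 182. The higher calls were 2 without control_4h replicate 1 or mid_4h replicate 2 and 8 without control_4h replicate 3.

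At 24 h Rsad2 changed by −3.05 ± 0.41 at the mid dose (SE, 4 against 5 animals, adjusted p = 5.02e-05), Bpgm by −2.80 ± 0.37, Fech by −2.54 ± 0.40 and Mki67 by −1.85 ± 0.39. Phlda3 rose by 0.54 ± 0.12, Tspan4 by 0.57 ± 0.11 and Socs3, an inhibitor of cytokine signalling, by 0.71 ± 0.19. The erythroid list had 16 of 35 genes lower (26 adjusted over the list alone), the heme list 9 of 12 (12), the cell cycle list 6 of 45 (34) and the p53 list 1 of 38 higher (5). Their medians were −1.69, −1.44, −0.81 and 0.14, with camera adjusted p = 3.82e-31, 9.93e-21, 3.56e-31 and 0.0153. With an estimated correlation they were 0.054, 0.054, 0.133 and 0.257. The first 3 lists were lower, and the p53 list higher, on each of 4 slides. limma called 11 probes higher and 446 lower, and 96 and 785 with slide as a block, which made all 457 calls in the same direction. The count was 283 without control_24h replicate 1, 134 without mid_24h replicate 1, 166 without control_24h replicate 2 and 179 without mid_24h replicate 2. The higher calls alone numbered 5, 3 and 5 without control_24h replicate 1, 2 or 5, 21 without control_24h replicate 3, and 2 and 3 without mid_24h replicate 1 or 2.

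At the low dose 0 probes were called by limma at 4 h, with 784 at an unadjusted p under 0.05 and a smallest adjusted p of 0.439. A block by slide gave 13 lower. Cdkn1a was 0.65 ± 0.18 higher (SE, 5 against 4 animals, adjusted p = 0.579) and higher on 4 of 4 slides, and Phlda3 0.40 ± 0.12 (0.778). The p53 list had 0 of 38 genes called (3 higher adjusted over the list alone) and a median of 0.05, with camera adjusted p = 0.00216, or 0.195 with an estimated correlation and 0.0274 when slide was a block as well. Its score was 0.10 ± 0.08 (SD, n = 5). The erythroid median was −0.0031 and the cell cycle median 0.18 (camera adjusted p = 0.00216, with an estimated correlation 0.956).

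At 24 h 51 probes were lower and 0 higher at the low dose by limma, with 1547 at an unadjusted p under 0.05. Rsad2 changed by −1.79 ± 0.39 (SE, 5 against 5 animals, adjusted p = 0.0397), Bpgm by −1.72 ± 0.35 (0.0294), Cyp4b1-ps2 by −2.30 ± 0.40 and Tent5c, which extends poly(A) tails, by −1.73 ± 0.30. Cy5 alone lost the calls of Rsad2 (limma adjusted p = 0.196) and Tent5c. Processed intensities lost those of Rsad2, Bpgm and Cyp4b1-ps2. The erythroid list had 1 of 35 genes lower (11 adjusted over the list alone), the heme list 0 of 12 (5) and the cell cycle list 0 of 45 (0), with medians of −0.80, −0.70 and −0.43. The p53 list had 0 of 38 genes called (2 higher adjusted over the list alone) and a median of 0.12. camera gave adjusted p = 5.47e-19, 4.31e-13, 3.45e-19 and 2.51e-04, and with an estimated correlation 0.145, 0.145, 0.277 and 0.1. A block by slide with an estimated correlation called the p53 list (0.0377). Each of these 4 lists moved the same way on 5 of 5 slides. A block by slide gave 6 higher and 213 lower, with all 51 calls among them in the same direction. The count without 1 array was 23 for control_24h replicate 1, 12 for control_24h replicate 2, 11 for low_24h replicate 1, 142 for low_24h replicate 2, 18 for low_24h replicate 3, 13 for low_24h replicate 4 and 24 for low_24h replicate 5.

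**Figure D2:**
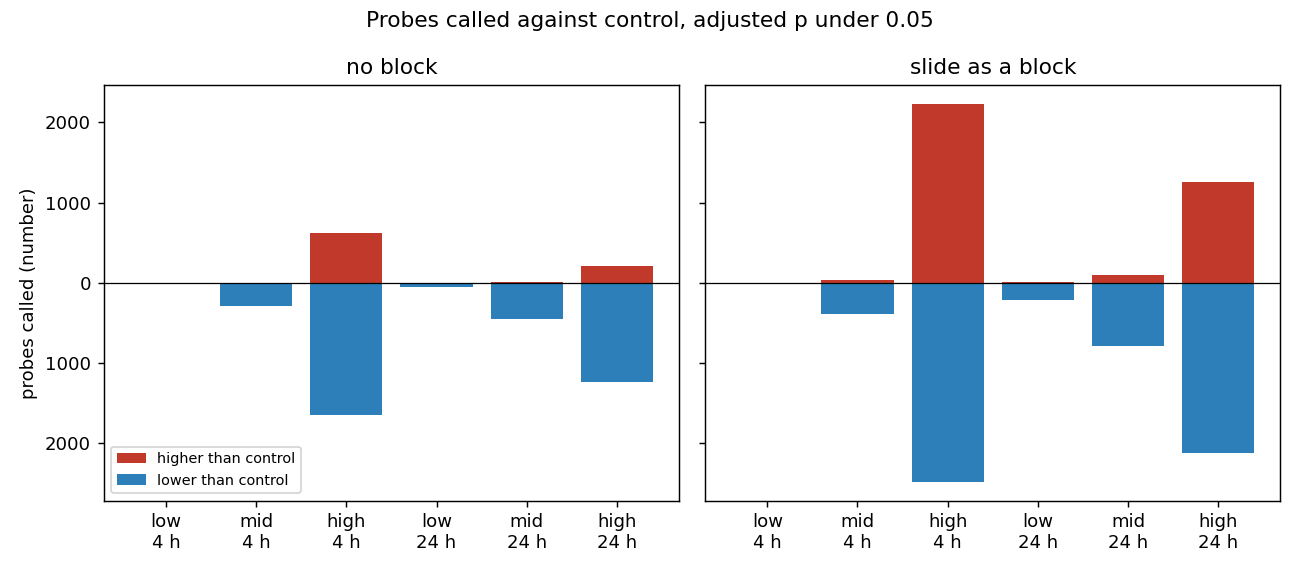
Number of probes called higher and lower (limma, adjusted p under 0.05) per dose and harvest time, without a block and with slide as a block. The calls without a block went from 0 at the low dose to 2272 at the high dose at 4 h, and from 51 to 1449 at 24 h.

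The dose trend was a single linear contrast over the 4 dose groups in order, given as a fitted slope per dose step. A change at the high dose alone can also meet it, so a call does not show a change at every step. For the dose trend, 4 h, limma called 902 probes higher and 1992 lower, and for the dose trend, 24 h, 283 and 1291. With slide as a block the counts were 3003 and 2867 at 4 h and 1443 and 2192 at 24 h, so that the share lower was 48.8% against 68.8% and 60.3% against 82%. With the pancreas score of each array as a covariate, a setting chosen after seeing the data, the share lower in the dose trend, 4 h, was 58.2%. The erythroid genes changed by a median of −1.15 per dose step at 4 h (32 of 35 lower) and −0.99 at 24 h (29 of 35), and held with an estimated correlation (adjusted p = 0.0132 and 0.011). So did the heme (0.0289 and 0.0167) and cell cycle lists (0.0301 and 0.0334). In all 10 comparisons, the only camera calls that held with an estimated correlation were those of these 3 lists at the high dose and in the trends. With slide as a block as well, the erythroid list held in both trends (0.048 and 0.0476). The p53 list had 5 genes higher and 1 lower in the 24 h trend, with adjusted p = 0.133 with an estimated correlation. Without control_4h replicate 1 the 4 h count was 1821, of which 309 were higher and 83% lower. The higher calls of the 24 h trend were 145, 146 and 151 without control_24h replicate 1, 2 or 5, and 154 without high_24h replicate 2.

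The effect of the high dose was then compared between harvest times. Across 14090 genes, which are not independent replicates, the changes at 4 h and 24 h correlated at r = 0.887, where simulated unchanged groups gave 0.00173. No control animal was shared. The groups did share slides, which the simulations left out, so the simulated values here and below do not show what shared slides alone would give. In both lists of calls 713 genes were lower, where independent lists of these sizes would share 54.2, and 82 were higher, where they would share 4.66. No gene was called in opposite directions, and over the genes called at either time the slope of the 24 h changes on those at 4 h was 0.816. limma called 0 probes for a difference between the times, with 356 at an unadjusted p under 0.05 and 0 with slide as a block. Within the mid dose the times correlated at r = 0.758, with 95 genes lower in both lists of calls against 2.09 for independent lists, and within the low dose at r = 0.438 with 0 genes called at 4 h. Comparisons within a harvest time share their controls. The mid and high doses at 24 h correlated at r = 0.893 (covariance 0.116) against 0.483 (0.0195) for simulated unchanged groups with shared controls, and at 0.654 with the controls split. At 4 h they correlated at 0.787 (0.0996) against 0.52 (0.0231) and at 0.54 with the controls split. The low and high doses at 4 h did not go together in this way, with r = 0.105 (0.0103) against 0.552 (0.0233) for simulated unchanged groups and −0.043 with the controls split. At 24 h the low and high doses correlated at 0.805 (0.0783) against 0.5 (0.0192) and at 0.493 with the controls split.

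**Figure D3:**
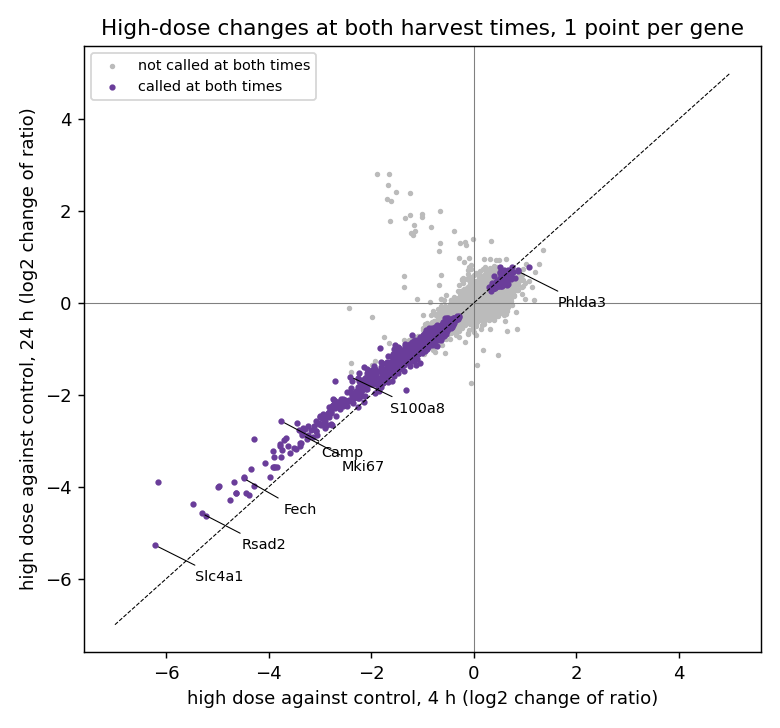
Log2 change at the high dose at 24 h (vertical axis) against 4 h (horizontal axis), 1 point per gene, with the genes called at both times in purple and the line of equal change dashed. The called genes lie at the lower left and upper right, with Slc4a1 at −6.21 and −5.27 and Phlda3 at 0.87 and 0.69.

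The control animals of the 2 harvest times were compared to see what time alone changed. limma called 0 probes, with 1059 at an unadjusted p under 0.05, and the smallest adjusted p was that of Cirbp at 0.79 ± 0.15 (SE, 5 against 4 animals, 0.185), followed by Dbp at 0.72 ± 0.15 (0.221). With slide as a block Cirbp alone was called, at 0.76 ± 0.11 (adjusted p = 0.00776). The cell cycle median was −0.11 and the stroma median 0.19, each with camera adjusted p = 0.0176, and with an estimated correlation 0.974 and 0.704. The block by slide took the cell cycle list to 0.209.

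The channels were also examined apart, since the reference channel holds the same RNA on every array. Their values had been dye-normalized by the scanner program, so neither channel was free of that step. At the high dose 19 probes were called in Cy3 at 4 h and 14 at 24 h, 10 and 8 of them in the erythroid and heme lists, and all moved in the same direction in Cy5. Alas2 changed by −9.57 in Cy5 and by −8.40 in Cy3 at 4 h, against −4.29 in the ratio. The alpha-globin gene Hba-a1 changed by −6.64 in Cy5 and −5.50 in Cy3 at 4 h, against −1.75 in the ratio. At 24 h Hba-a1 stood at −0.74 in the ratio (adjusted p = 0.32) and at −4.29 in Cy5 (3.5e-06). Bpgm at −5.65 in Cy5 and −0.43 in Cy3 and Fech at −4.60 and 0.17 were called at 4 h in Cy5 and not in Cy3. Slc4a1 changed by −9.73 in Cy5 and −3.48 in Cy3 at 4 h (Cy3 adjusted p = 9.77e-04), against −6.21 in the ratio, and Hbb-bs by −8.97 and −6.36, against −6.15. For these 4 genes the ratio thus changed less than the spleen channel did, and the ratios given for them here carry that limit. In Cy5 alone the erythroid median was −5.70 at 4 h and −4.40 at 24 h, with 32 of 35 genes lower at each time. The cell cycle medians in Cy5 were −1.94 and −1.77.

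**Figure D4:**
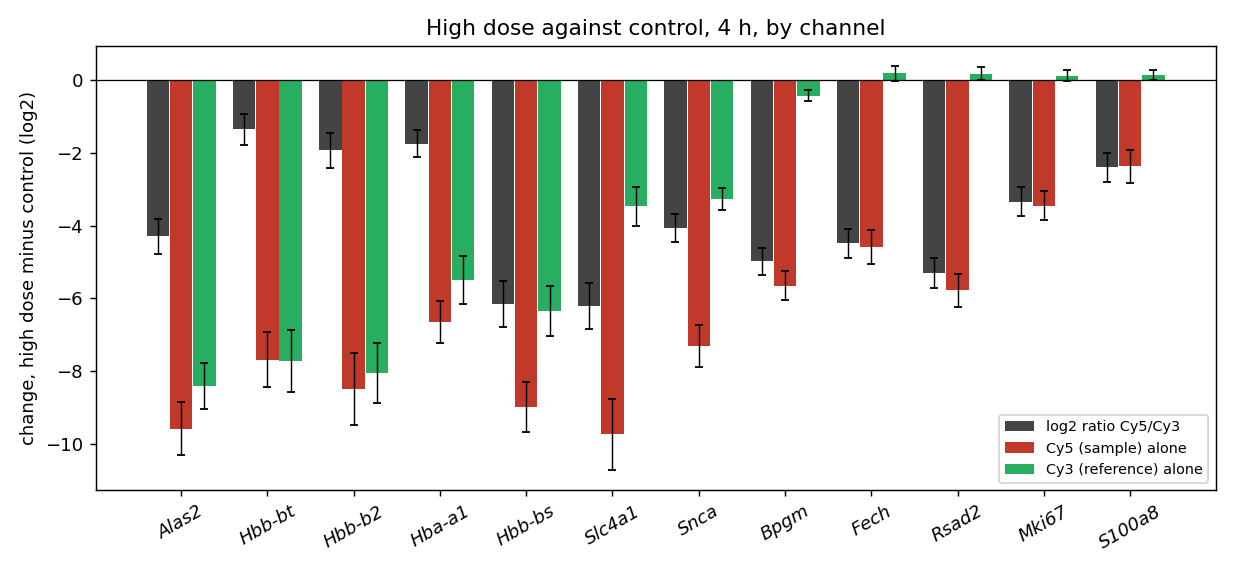
Change at the high dose and 4 h (log2, ± SE, 5 against 4 animals) of 12 genes in the ratio, in Cy5 and in Cy3. The channels come from the processed intensities and the ratio from background-corrected median signals, so they do not add up. Alas2 and Hba-a1 fell in both channels, while Bpgm, Fech and Mki67 (−3.46 in Cy5 and 0.11 in Cy3) were called in Cy5 and not in Cy3.

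Genes of the pancreas list, 2 of them the insulin genes Ins1 and Ins2 and most of the others exocrine, differed between animals of the same group. The pancreas score of the 24 h control animals ran from −2.00 to 3.37 around a mean set to 0 (SD 2.72, n = 5), and the low-dose groups had means of 2.42 ± 2.10 at 4 h and 2.23 ± 2.35 at 24 h (SD, n = 5). The list had 0 of 24 genes called at every dose and time, but camera gave adjusted p = 4.31e-16 for the low dose at 4 h and 5.02e-12 at 24 h, with medians of 2.59 and 2.38. With an estimated correlation these were 0.523 and 0.352. The list was also higher at 24 h at the mid dose (median 1.29, camera adjusted p = 0.0243, with an estimated correlation 0.659, with slide as a block 0.106) and at the high dose (1.62, 0.0182, 0.681). Between the slides the low-dose difference at 4 h ran from −2.60 to 4.85 and was higher on 3 of 4. At 24 h it was higher on 5 of 5 slides at the low dose (0.097 to 4.85) and at the high dose (0.021 to 4.58) and on 3 of 4 at the mid dose, while at the high dose and 4 h it was lower on 3 of 4 (−2.58 to 0.24).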

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

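The tests of another reference RNA, of slides, of the ratio and its normalization, and of all explanations for the pancreas genes were chosen only after the results had been seen, while the splits and the test of channel bleed-through were set beforehand.

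Splits of the same arrays into groups of the same sizes, with the real split as 1 of them, were counted for each comparison. The splits moved arrays freely between slides and used the fit without a block. With the real split counted, 1 of 35 or 1 of 100 is the smallest share they can give. No correction was made over the comparisons, so the splits argue against chance but cannot exclude it. The real split alone called as many probes for the mid dose at 4 h (1 of 35, real 287, highest other 0) and the high dose at 4 h (1 of 100, 2272 against 1282). At 24 h the real split alone did so for the low dose (1 of 100, 51 against 24), the mid dose (1 of 100, 457 against 299) and the high dose (1 of 100, 1449 against 790). The same holds for the dose trend at 4 h (1 of 100, 2894 against 38) and at 24 h (1 of 100, 1574 against 2). For the low dose at 4 h, the difference of the high-dose effect between times and the control animals of both times the real count was 0, so that 100 of 100 splits gave as many by construction and say nothing for or against chance. The highest other counts there were 157, 2 and 20, with a median of 0. A split of the low-dose and control arrays at 4 h that called 157 probes points to a structure of the samples. The slides, with 31.1% of the variance, are a candidate source. Another is the pancreas score, with which 2639 probes rose and 1785 fell in a fit of group means without slides. Neither was tested on that split.

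A signal in the reference channel drew attention because the Cy3 RNA was the same on every array, yet limma called 19 probes in Cy3 at the high dose at 4 h and 14 at 24 h. Another reference RNA in the dosed groups is argued against, since 19 of 19 probes moved in the same direction in Cy5. Bleed-through of bright Cy5 signal into Cy3 was tested on 24 pancreas probes, whose Cy5 signal differed by a median of 11.4 on the log2 scale between the 5 brightest and 5 dimmest arrays. Their Cy3 signal differed by a median of 3.00, and 24 of 24 lay above 0, so bleed-through is a candidate explanation that stays open. Both tests rest on dye-normalized intensities, and dye normalization is another candidate that was not tested. No biological explanation was tested, since the reference RNA was the same in every group.

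The fall of erythroid and cell cycle genes at the high dose was weighed against technical sources. Both tests used the erythroid list alone. For the erythroid genes slides are argued against, since the smallest fall of the erythroid score of a high-dose array against the control of its slide was −1.67. The smallest such fall of the cell cycle score was −0.82, at 24 h. The cell cycle list was not called with slide as a block and an estimated correlation, so slides are not settled for it. The ratio to the reference and its loess step are argued against for the erythroid genes. Their median in Cy5 alone was −4.40 at the time with the smaller fall. That Cy5 signal had been dye-normalized by the scanner program, so the test cannot decide on dye normalization. An effect of DBC on red-cell precursors and dividing cells may explain it and stays a hypothesis, found and tested on the same data. Whether such cells were fewer or held fewer of these transcripts was not tested.

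Pancreas genes differed between animals of the same group. A response to the dose as the whole cause is argued against by a span of 5.37 on the log2 scale among the control animals of 1 harvest time, but a partial one stays open, since the list was higher on 5 of 5 slides at 24 h at the low and at the high dose. Slides are argued against by a span of at least 4.23 within every slide. Pancreas tissue taken along with the spleen may explain it, since 10 of 13 acinar genes outside the list rose with the pancreas score, among them Gp2 by 0.93 and Spink1 by 0.85 per log2 unit. In the same fit 1079 genes outside the list rose, of 14090 genes in all. An islet list tried first, which left out the insulin genes of the pancreas list, had only 1 of 9 genes measured, Pcsk2, which did not rise, and decided nothing, while 0 of the 24 pancreas genes were in another list and their own expression in spleen was not tested.

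Single arrays stood far from the rest of their group in a list score, by Dixon's test of the gap to the nearest array at its 95% critical value, in 10 of 128 combinations of the 16 lists described in the report with the 8 groups. Chance gives about 1 in 20 by the level of that test. They were heme synthesis in high_24h replicate 4 (−1.61), neutrophils in control_4h replicate 2 (0.75) and low_4h replicate 3 (0.43), NRF2 targets in low_24h replicate 3 (−0.29) and mid_4h replicate 2 (−0.34), B cells in low_4h replicate 5 (−0.69), stroma in low_24h replicate 5 (−0.24), interferon response in mid_4h replicate 1 (−0.27), and pancreas in low_24h replicate 5 (−1.88) and low_4h replicate 1 (−1.28).

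By camera with its preset correlation, 7 lists differed between 24 h and 4 h in the effect of the high dose. The medians of the difference were 0.064 for DNA repair, 0.22 for cell cycle, 0.46 for erythroid, 0.21 for heme synthesis, −0.30 for stroma, 0.17 for glucocorticoid and 2.73 for pancreas genes. With an estimated correlation their adjusted p lay between 0.466 and 0.903 and none was called, and with slide as a block DNA repair (0.099) and heme synthesis (0.113) were not called either.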

How the results depend on the processing

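The pancreas score as a covariate was the only setting here chosen after the results had been seen. No named gene that was called in either fit changed sign, and no list called in both did. A list that lost its call was counted as weaker whatever its direction. The majority of calls did turn from lower to higher under a block. For the dose trend at 4 h 48.8% were lower with slide as a block, against 68.8%. Without background subtraction, from the deposited table and with the stricter filter, every total count stayed within 1.5 times, though the number of higher calls for the mid dose at 24 h was 11 and without background subtraction 6. Processed intensities gave 15 probes for the low dose and 289 for the mid dose at 24 h, and 364 higher calls for the high dose at 24 h. Cy5 alone gave 160 (16 higher) for the mid dose at 4 h, 21 for the low dose at 24 h and 1 for the difference of the high-dose effect between times. Cy5 alone and no filter each gave 7 higher calls for the mid dose at 24 h. No filter gave 24 and array weights 128 for the low dose at 24 h. Array weights moved the higher calls more than the totals, to 10 and 1180 for the mid and high dose at 4 h, 23 and 491 for the mid and high dose at 24 h, and 1463 and 545 for the trends. A fold change of at least 1.5 left 1370 for the high dose at 4 h and 342 and 209 for the trends at 4 h and 24 h, fewer by construction. Each time fitted alone gave 170 for the mid dose at 4 h, and could not be run across times. Slide as a block gave 13, 4711, 219, 881 and 3371 for the low and high dose at 4 h and the low, mid and high dose at 24 h, 5870 and 3635 for the trends and 1 for the controls. The pancreas covariate gave 1 for the difference between times and 9 for the controls, and raised the higher calls to 966 for the high dose and 1500 for the trend at 4 h. For slide as a block, the main fit had kept the 31.1% of the variance between slides in its error, beside the 30.7% left. Otherwise, apart from the fold threshold, the cause was not tested.

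Replicate number as a block gave 7 for the low dose at 4 h, 6168 for the high dose at 4 h, 102 for the low dose and 2487 for the high dose at 24 h, 6528 and 2725 for the trends and 1 for the difference between times. It gave 18 and 40 higher calls for the mid dose at 4 h and 24 h. With it 3505 calls were higher and 2663 lower for the high dose at 4 h (43.2% lower against 72.8%), 3662 and 2866 for the 4 h trend (43.9%), 776 and 1711 for the high dose at 24 h (68.8% against 85.6%) and 943 and 1782 for the 24 h trend (65.4% against 82%). It could not be fitted for the controls, since the block lies within harvest time. The numbers were not shown to pair the animals. At 24 h, where the number was also the slide, 25 of 27 pairs of the same number correlated above 0.1. At 4 h 14 of 25 did, with a median r of 0.144, and 11 of the 25 pairs lay on different slides. Of the 4 h pairs on the same slide, 21 of 24 did, with a median r of 0.403. The 4 h correlations thus went more with the slide than with the number.

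Leaving out 1 array gave 0 to 1 for the low dose at 4 h (1 without control_4h replicate 3 or low_4h replicate 5), 154 to 384 for the mid dose at 4 h (182 without mid_4h replicate 4 and 161 without mid_4h replicate 2, the lowest without control_4h replicate 2) and 1343 to 2411 for the high dose at 4 h (lowest without control_4h replicate 1). At 24 h it gave 11 to 142 for the low dose, 134 to 546 for the mid dose and 975 to 1644 for the high dose. The trends gave 1821 to 3277, the lowest without control_4h replicate 1, and 1101 to 1784. The difference between times and the controls stayed at 0.

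Of the settings for named genes, 10214 values kept direction and side of the threshold, 151 were weaker, 209 stronger and 93 moved. Of the list tests, 830 kept their side of the threshold, 181 were weaker and 29 stronger. Direction was not compared for lists called in neither fit. Of 260 list tests each, an estimated correlation made 89 weaker, fry 64 weaker and 8 stronger, slide as a block 15 weaker and 5 stronger, and Cy5 alone 13 weaker and 16 stronger. At the low dose fry called no list, and at the high dose and 4 h it called the AHR list higher (adjusted p = 0.00869), which camera did not. Slide as a block made 54 of the gene values stronger. Among genes named in the report, Cy5 alone lost the calls of Cirbp at the mid dose and 4 h, of Ephx1 at the high dose and 4 h, of Phlda3, Tspan4 and Socs3 at the mid dose and 24 h, of Rsad2 and Tent5c at the low dose and 24 h, and of Ccng1 and Zap70 at the high dose and 24 h. Processed intensities lost those of Alas2 at the high dose at both times, of Adcy5 at the high dose and 4 h, of Ppm1d at the high dose and 24 h, of Cirbp at the mid dose and 4 h, of Socs3 at the mid dose and 24 h, and of Rsad2, Bpgm and Cyp4b1-ps2 at the low dose and 24 h. The deposited table lost Cdkn1a and Ccng1 at the high dose and Socs3 at the mid dose, all at 24 h. At the high dose and 4 h, 1495 probes were called both in the ratio and in Cy5 alone. Probes with little signal over background in Cy5 were tested only in the fit with no filter. Changes in dim genes such as Cyp1a1 could therefore not be seen in the main fit.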

Other observations

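The test of Rsad2 against the erythroid and interferon scores was set before its result was seen, for a fall of Rsad2 already found in these data. No prediction was set beforehand for the Isg15 relations.

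The remaining gene lists gave few calls at the high dose. Dendritic cell genes had 1 of 16 lower at each time, Zbtb46 at −1.22 ± 0.21 and −1.06, with medians of 0.10 and 0.07 (the mean at 24 h was −0.03). Progenitor genes had 2 of 13 higher and 1 lower at 4 h, with Ly6a at 0.74, Cd34 at 0.59 and Myb at −1.22 ± 0.22, and a median of 0.19 (4 higher and 2 lower adjusted over the list alone). At 24 h 1 was higher and 1 lower, with a median of 0.11 (2 and 1). Plasma cell genes had 2 of 14 higher and 1 lower at 4 h (median 0.22) and 0 called at 24 h (0.13), with 2 higher and 1 lower and 1 higher and 1 lower adjusted over the list alone. By limma 0 genes were called at either time among 18 NK and cytotoxic genes (0.15 and 0.08), 21 megakaryocyte and platelet genes (0.13 and 0.15), 7 germinal centre genes (0.07 and 0.23), 17 inflammatory genes (0.26 and 0.16), 18 immediate early genes (0.0043 and 0.06), 10 adipose genes (0.23 and 0.17) and 6 muscle and liver genes (0.19 and 0.02). Camera gave none of these lists an adjusted p under 0.05 at the high dose.

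The preset-correlation test also called further lists at the lower doses, and none of them held with an estimated correlation. At the mid dose and 24 h these were T cells (median 0.29, adjusted p = 2.61e-04, with an estimated correlation 0.52), macrophages (0.22, 0.00528, 0.52), B cells (0.23, 0.00475, 0.548), NK cells (0.20, 0.0307, 0.604), neutrophils (0.28, 0.0396, 0.604), inflammatory genes (0.23, 0.0239, 0.446) and DNA repair (−0.14, 0.00475, 0.37). At the low dose and 24 h they included interferon response (0.25, 3.79e-04, 0.458), glucocorticoid response (0.19, 0.0016, 0.145) and macrophages (0.15, 0.00573, 0.649). The low dose at 4 h gave B cells at −0.12 (0.0131, 0.956), immediate early genes at −0.13 (0.0131, 0.584) and stroma at 0.16 (0.0106, 0.584). At the mid dose and 4 h stroma stood at 0.23 (0.0013, 0.294), B cells at 0.17 (0.00649, 0.797) and interferon response at −0.021 (0.0472, 0.797). Between the control animals, muscle and liver genes were lower at 24 h (−0.62, 0.0046, 0.704), as were plasma cell genes (−0.10, 0.0176, 0.704). With slide as a block the NK (0.192) and neutrophil (0.179) lists at the mid dose and 24 h, the immediate early genes at the low dose and 4 h (0.101) and the plasma cell genes of the controls (0.0634) were no longer called.

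Rsad2 fell while most interferon response genes did not. The hypothesis that Rsad2 follows the erythroid genes was tested across 37 arrays with group and slide means removed, in a family of 4 relations with Isg15. The permutations treated the 37 residuals as independent although these means had been removed. The permutation p-values given here are therefore too small. Rsad2 correlated with the erythroid score at r = 0.908 (permutation p = 1e-05, the smallest the permutations can give, adjusted 4e-05, Spearman's rho 0.909, p = 1e-05), at r = 0.902 without the 2 farthest arrays and between 0.871 and 0.949 within slides. With the interferon score it correlated at r = −0.334 (p = 0.042, adjusted 0.056, rho −0.322, p = 0.052, without the 2 farthest −0.331, within slides −0.864 to 0.296). Isg15 correlated with the erythroid score at r = 0.622 (p = 5e-05, adjusted 1e-04, rho 0.652, p = 4e-05, without the 2 farthest 0.621, within slides 0.531 to 0.764) and with the interferon score at r = 0.145 (p = 0.39, adjusted 0.39, rho 0.169, p = 0.31, without the 2 farthest 0.105, within slides −0.417 to 0.616). The heme synthesis, cell cycle and neutrophil scores, which also fell at the high dose, were not tried. The relation is therefore not shown to be particular to the erythroid genes. Loss of cells or transcripts of the erythroid lineage may account for the fall of Rsad2 and stays a hypothesis. Which spleen cells express Rsad2 was not measured.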
